A study of Arabidopsis thaliana with 6 samples.

How the data were processed

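Transcript abundance was measured in leaves of Arabidopsis thaliana, accession Col-0, on 6 Affymetrix ATH1 arrays, each hybridised with biotin-labelled total RNA of 1 sample. Per the labels, plants grew in compost in a growth room at 22 °C and 70% humidity with 18 h days, were watered 3 times a week, and gave 2 mature rosette leaves at growth stage 3.90. Samples were grouped by the treatment in the labels, with 3 control arrays (no treatment) and 3 aphid arrays (10 aphids held in cages on 2 rosette leaves for 8 h). The labels name neither the aphid species nor a cage on control leaves, so the effects of aphids and of the cage cannot be told apart. Nothing in the labels says that replicates came from separate plants, so p-values measure the spread between these samples, which may be technical.

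The deposited values are linear signal intensities per probe set, made by the authors with MAS5 per the submitters' processing notes; its version, the scanner settings and detection calls are not given in the sources used here. The mean signal after trimming 2% of probe sets at each end was 100.0 on all 6 arrays, and median signals of non-control probe sets lay between 41.8 and 44.2, so absolute differences in total RNA cannot be read from these values. MAS5 signals of dim probe sets vary widely on a log scale, which is why dim probe sets were left out of the tests. Arrays carry no read depth; the number of arrays limits the precision.

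Of 22810 probe sets, 64 were Affymetrix controls and were used only for quality. In the platform annotation used here, 13513 probe sets had 1 gene symbol, 503 had several and were left unnamed, and 8730 of the non-control probe sets had none and are unnamed here. Symbols of 13436 probe sets were updated through a RefSeq gene table of assembly TAIR10.1. That table served for names, for pairing gene list members with probe sets by locus code, and for which genes are plastid-encoded. Since no genome build is named for the values, no coordinates are given. Signals were transformed as log2(signal + 1), which understates the differences of dim genes, and the upper 60% of non-control probe sets by mean over all arrays were tested (13647 probe sets, 7447 of them with 1 gene; lowest mean signal 27.5).

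Aphid arrays were compared with control arrays in limma 3.58.1 under R 4.3.3, with lmFit and eBayes with an intensity trend, 2-sided, and Benjamini-Hochberg adjustment over all tested probe sets at 0.05. Standard errors (SE) and 95% confidence intervals are those of limma on the log2 scale, without the replicate block described below unless stated. SD refers to linear signals. Gene lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, with an estimated correlation and fry beside it; each gene was represented by its brightest probe set. The design, the alternatives, 20 gene lists with 387 members and the rule for named genes were fixed before the data were examined. The lists covered salicylic acid, jasmonate, ethylene, abscisic acid and water deficit, touch and calcium, indole and aliphatic glucosinolates, cell wall, phloem and sugar transport, oxidative stress, photosynthesis, the circadian clock, darkness and senescence, heat shock, phenylpropanoids, auxin, and markers of guard cells, epidermis, xylem and dividing cells. Of the members, 3 were dropped because the RefSeq table gives their symbol to another locus. A probe set of 1 gene was found for 47, and 36 in 16 lists were bright enough to be tested. The lists for oxidative stress, darkness and senescence, epidermis and xylem had 0 tested members and gave no result. Named genes were all genes past the adjusted threshold, up to 30 of them. With fewer past it, up to 10 genes per direction with the smallest p were added, at a difference of at least 2-fold and with groups that did not overlap, and the 2 members of each list with the smallest p. This gave 32 genes.

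Control and aphid arrays share replicate numbers. Deviations from the group means correlated between arrays of the same number at 0.300, 0.549 and 0.312 for numbers 1, 2 and 3, and between arrays of different numbers from -0.389 to 0.146 (across genes, which are not independent replicates). As each same-number correlation was above 0.1, the numbers were taken to pair the arrays, though control 1 with aphid 3 reached 0.146 too. Deviations cancel out within a group, so the same-number and different-number correlations are not independent evidence. The pairing comes from the values, and the labels do not say what a number marks. The fit with the number as a block was a fixed alternative, and its values stand beside a result where they change a call or move a count by over 1.5 times. Its SE is also given for some genes where it was much smaller. On simulated data made from these arrays (10 runs, 200 changed probe sets of 13647 in each), the fit without the block called 60% of 2-fold and 98.2% of 4-fold changes, and 0.0632% of its calls were false. The fit with the block called 95.7% and 100% of them, and 8.38% of its calls were false. The simulation took the measured means of each number as true and added noise to them. It can therefore overstate differences between numbers, understate what the fit without the block calls, and favour the block.

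Alternatives were pseudocounts of 16 and 64, no filter, a filter keeping the upper 40%, quantile normalization, centring on the median, no variance trend, robust variance, array weights, the replicate block, leaving out each array in turn, an adjusted threshold of 0.1, an estimated correlation and fry. After the data were seen, fits without both arrays numbered 2, the block with quantile normalization or with the threshold of 0.1, all list members as 1 list, families of gene symbols, and an F test of the replicate number were added.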

Results

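Leaf transcripts of Col-0 plants were compared between 3 samples from leaves on which 10 aphids had been caged for 8 h and 3 samples from untreated leaves, on ATH1 arrays with 13647 probe sets tested. The series addresses how plants and insects interact at the molecular level, and this contrast asks which leaf transcripts differ after a short period of aphid feeding.

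AT1G66760 had a signal of 49.9 ± 9.39 on the aphid arrays and 22.3 ± 11.2 on the control arrays (SD, n = 3 each), a log2 difference of 1.23 (SE 0.34). AT4G16000 was 1.61 (SE 0.54) and AT3G14750 1.06 (SE 0.39) higher on the log2 scale on the aphid arrays. In the other direction, PRA1.B4, of the prenylated Rab acceptor family, had a signal of 76.9 ± 29.1 on the aphid arrays and 152 ± 22.5 on the control arrays (SD, n = 3 each), a log2 difference of -1.03 (SE 0.24). AT4G16563 had a log2 difference of -1.10 (SE 0.33). These 5 genes were picked by rule for groups that did not overlap, and none passed the adjusted threshold (limma, p between 0.00250 and 0.0232, adjusted p = 0.986 each). Single arrays and the scale moved their sizes. AT4G16000 was at 0.96 without control replicate 3 and AT3G14750 at 0.61 without control replicate 1. AT4G16563 was at -0.69 without both arrays numbered 2 (a choice made after the data were seen). With a pseudocount of 16, AT1G66760 and AT4G16000 were at 0.81 and 0.99. AT4G16000 lay close to the brightness filter, and some fits that left out an array gave no value for it. With a pseudocount of 64, AT1G66760, AT4G16000, AT3G14750, PRA1.B4 and AT4G16563 were at 0.40, 0.48, 0.38, -0.63 and -0.64. The control signals of AT4G16000 (18.8 ± 12.7, SD, n = 3) and AT1G66760 lay below 27.5, the lowest mean signal among tested probe sets. That lowest mean was taken on the log2 scale, where the control mean of AT3G14750 (linear 27.9 ± 14.2, SD, n = 3) lay below it too. The sizes of the differences of AT4G16000, AT1G66760 and AT3G14750 are therefore uncertain. Over all tested probe sets, groups did not overlap in 9.40%, where chance gives 10% for 3 arrays against 3. All 3 same-number pairs went in 1 direction in 32.2%, where chance gives 25% (genes are not independent).

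Of the 13647 probe sets, 0 passed an adjusted p of 0.05 in limma, and the smallest adjusted p was 0.986. At an unadjusted p under 0.05 there were 567 probe sets, 233 of them higher and 334 lower on the aphid arrays, where evenly spread p-values give 682. Differences between replicate numbers stay in the spread of this fit, so 682 need not be its chance count. Other splits of the arrays that part all same-number pairs gave 218, 261 and 343, and are too few for a test. A difference of at least 2-fold at an unadjusted p under 0.05 was seen in 10 probe sets, 7 higher and 3 lower; leaving out single arrays gave 6 without control replicate 1, 39 without control replicate 2, 22 without aphid replicate 1, 17 without aphid replicate 2 and 16 without aphid replicate 3. The median SE of a log2 difference was 0.157 (0.132 with the block), and the 95% interval of 95.8% of probe sets lay within 2-fold in either direction. On simulated changes the fit without the block called 60% of 2-fold differences, a share that the simulation may understate because it can overstate differences between numbers.

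With the replicate number as a block, 0 probe sets passed 0.05, the smallest adjusted p was 0.0631, and 1380 had an unadjusted p under 0.05 (667 higher, 713 lower; 10.1%, where chance gives 682), of which 549 were among the 567. At a threshold of 0.1, chosen for this fit after the data were seen, 7 probe sets passed, all higher on the aphid arrays. All 7 also differed between replicate numbers (limma F test, adjusted p between 0.00028 and 0.030), as did 5.44% of all tested probe sets. On the simulated data, 8.38% of the calls of this fit at 0.05 were false. Of these 7, 3 carry 1 gene symbol and were likewise singled out after their values were seen. AT2G29670 had a log2 difference of 0.70 (SE 0.09 with the block; limma adjusted p = 0.0631), with 0.66, 0.67 and 0.76 in the 3 pairs. AT1G20070 had 0.81 (SE 0.11; adjusted p = 0.0666), and SIS 1.05 (SE 0.15; adjusted p = 0.0666). The other 4 are unnamed here and were at 0.75, 0.81, 1.09 and 0.70. Among these 4, groups did not overlap for those at 0.81 and 1.09. They overlapped for the other unnamed probe sets and for AT2G29670, AT1G20070 and SIS. Without the block, the SE of AT2G29670 was 0.43 and its adjusted p 0.986.

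The platform annotation and the RefSeq table pair 47 of the 387 list members with a probe set of 1 gene. Most standard markers of these pathways were therefore not analysed here. Of the 36 tested members, 23 had positive and 13 negative differences, between -0.68 and 0.36 on the log2 scale with a median of 0.08, and 0 passed the adjusted threshold. Taken as 1 list, they did not pass (limma camera, adjusted p = 0.153), and the 95% interval lay within 2-fold for 30 of them. At an unadjusted p under 0.05 there were 2 of the 36, and 6 with the block.

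The cell wall list, tested with 5 members, was lower on the aphid arrays (limma camera, adjusted p = 0.0355 over the 1 list with enough members; median log2 difference -0.46, mean -0.29), with 4 of 5 members negative. The call was lost with an estimated correlation (limma camera, adjusted p = 0.0986, and adjusted p = 0.150 with the block). The correlation estimated without the block was -0.029, below the preset 0.01, so correlated members do not account for the loss in that fit. The test with an estimated correlation has few degrees of freedom here, so it cannot decide whether the list shifted. XTH16, a xyloglucan endotransglucosylase/hydrolase, had a signal of 35.4 ± 2.19 on the aphid and 58.7 ± 16.6 on the control arrays (SD, n = 3 each), a log2 difference of -0.68 (SE 0.20; limma adjusted p = 0.986, and 0.0455 adjusted over the list alone). ATPMEPCRB, a pectin methylesterase, was at -0.47 (SE 0.19) and XTH33 at -0.46 (SE 0.31), while the expansins EXPA4 and EXPA8 were at 0.00 and 0.16. The 5 tested genes with symbols in EXPA, grouped after the data were seen, had a median of 0.16, with 3 positive and 2 negative. As a group they did not pass (limma camera, adjusted p = 0.155 over 28 families). Over all genes 0 members passed, and 1 (XTH16) passed adjusted over the list alone; with the block 2 did, ATPMEPCRB being the other. Fry in limma, which does not compare the list with other genes, gave an adjusted p = 0.0767 for a shift in 1 direction and an adjusted p = 0.0406 for changes in either direction. The camera call was also lost with a pseudocount of 64 (adjusted p = 0.0731), with no filter (adjusted p = 0.184 over 3 lists, from 0.0613 before adjustment), and without control replicate 1 (adjusted p = 0.0813), control replicate 3 (adjusted p = 0.0735) or aphid replicate 3 (adjusted p = 0.0854). The median was -0.18 with a pseudocount of 64, -0.14 without control replicate 1, -0.30 without aphid replicate 2 and -0.25 without both arrays numbered 2. The aphid arrays also had higher actin 3′ to 5′ signal ratios than the control arrays, at 1.67 to 1.75 against 1.42 to 1.56, while the GAPDH ratios overlapped (0.761 to 1.05 against 0.890 to 0.962), as did those of ubiquitin (1.67 to 1.92 against at most 1.72).

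Of the defence hormone lists, 2 of 20 salicylic acid, 1 of 25 jasmonate and 1 of 23 ethylene members were tested, too few to describe these pathways, and 0 passed over all genes or adjusted over the list alone. For salicylic acid these were GRX480, a glutaredoxin, at 0.35 (SE 0.23) and SAG101, a partner of EDS1, at 0.02 (SE 0.25) on the log2 scale. For jasmonate, OPCL1, which activates precursors for beta-oxidation, was at 0.12 (SE 0.14). For ethylene, the transcription factor EIN3 was at 0.16 (SE 0.13). In the touch and calcium list, WRKY53 was at -0.04 (SE 0.32) and the zinc finger gene STZ at -0.01 (SE 0.19). The abscisic acid and water deficit list held COR15A at -0.18 (SE 1.01), LTI30 at 0.30 (SE 0.31) and COR47 at 0.02. With the block the SE was 0.13 for COR15A and 0.17 for LTI30. Of the auxin list, GH3.3, which conjugates auxin to amino acids, was at -0.29 (SE 0.38), IAA29 at 0.12 (SE 0.37) and WES1 at 0.02. For GH3.3 and IAA29 the SE with the block was 0.19 and 0.16. None of these touch, abscisic acid and auxin genes passed either.

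All 3 tested members of the aliphatic glucosinolate list had positive differences, with 0 past the threshold over all genes or adjusted over the list alone. AT2G31790, a glucosyltransferase of this pathway, was at 0.36 (SE 0.17), and BCAT4, which starts methionine chain elongation, at 0.30 (SE 0.21). Leaving out 1 array gave 0.22 (without aphid replicate 2) to 0.54 (without aphid replicate 1) for AT2G31790, and 0.10 to 0.51 without the same arrays for BCAT4. With the block, both passed adjusted over the list alone, and neither passed over all genes (adjusted p = 0.292 and 0.357). In the indole list, UGT74B1 was at 0.23 (SE 0.18) and AT2G04400, of tryptophan synthesis, at 0.12 (SE 0.16). Neither passed.

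Of the photosynthesis list, 4 members were tested, 3 positive and 1 negative, with RCA (rubisco activase) at 0.12 (SE 0.12) and PRK (phosphoribulokinase) at 0.10 (SE 0.12). After quantile normalization RCA and PRK were at 0.011 and 0.012. The sugar exporter SWEET11, the 1 tested phloem and sugar transport gene, was at 0.05 (SE 0.16), and the clock gene GI at -0.05 (SE 0.14). In the phenylpropanoid list, 3 of 3 members were positive, with DFR at 0.15 (SE 0.19) and UGT78D2 at 0.10 (SE 0.14). In the heat shock list, ATHSP22.0 was at 0.15 (SE 0.18) and HSA32 at -0.12 (SE 0.17). Markers of other cell types were FMA of guard cells at -0.30 (SE 0.18), and AUR1 at 0.15 (SE 0.19) and PRL at -0.41 (SE 0.31) for dividing cells. PRL was at -0.06 without aphid replicate 3 and -0.16 without control replicate 2, and AUR1 at 0.06 without aphid replicate 2 and 0.32 without aphid replicate 3. None of these lists had a member past the threshold over all genes or adjusted over the list alone, with or without the block. On leaving out 1 array, 28 of the 32 named genes moved by over 1.5 times or to the other sign, so single values without the block are imprecise. Each omission left 1 array without its same-number partner, so these moves include differences between numbers. For values near zero, a small shift also counts as a large move.

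**Figure D1:**
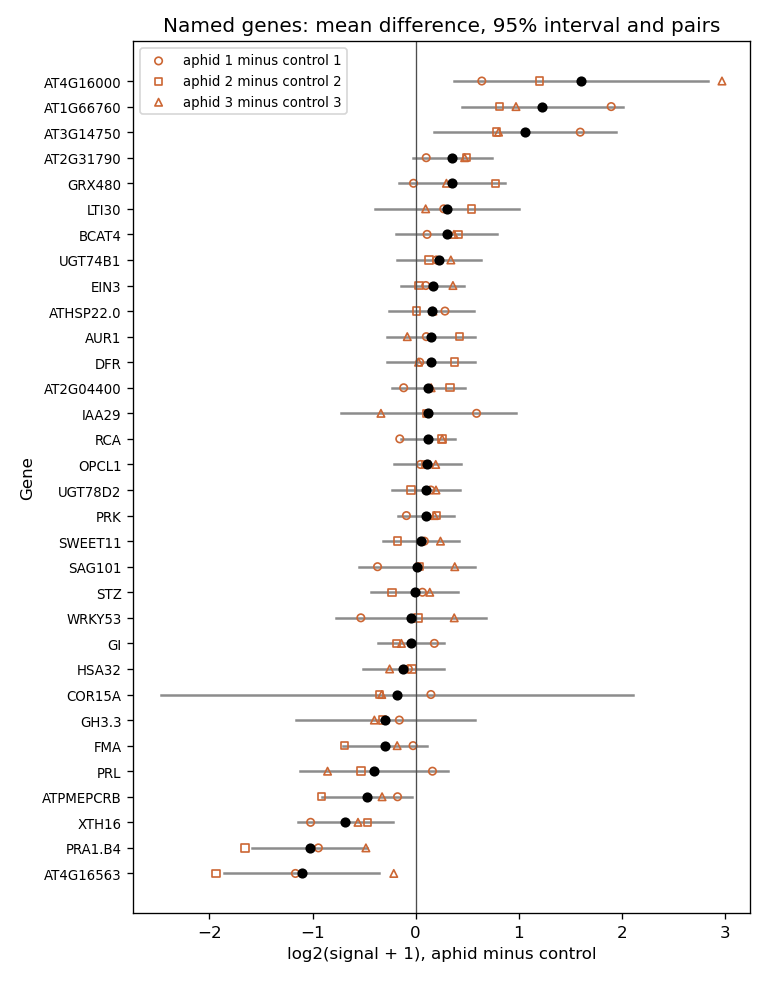
Log2 differences of log2(signal + 1), aphid minus control, for the 32 named genes (vertical axis). Filled points are means, horizontal lines limma's 95% intervals without the block, and open symbols the 3 same-number pairs. The interval of COR15A spans both directions by over 2 log2 units, with an SE of 1.01 (0.13 with the block).

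Both arrays of replicate number 2 stood apart from the rest. On the first principal component, with 40.6% of the variance, the control and aphid arrays numbered 2 scored 21.5 and 27.4, and the other 4 arrays between -14.5 and -6.71. Across non-control probe sets, arrays of 1 group correlated at r = 0.965 to 0.972 and arrays of different groups with the same number at 0.969 to 0.971, and arrays differing in both at 0.962 to 0.971, so these ranges overlapped (genes are not independent replicates).

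**Figure D2:**
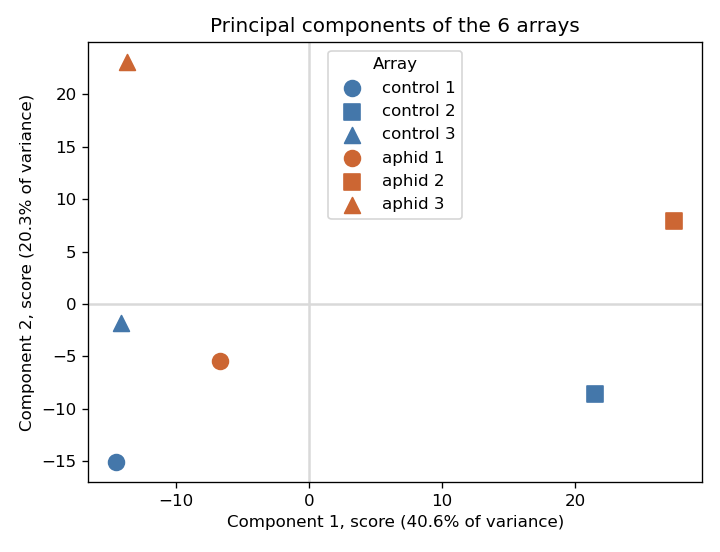
Scores of the 6 arrays on the first 2 principal components of the tested probe sets (arbitrary units); colour marks the group and shape the replicate number. Both arrays numbered 2, at 21.5 and 27.4, lie to the right of the other 4.

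COR15A, a cold- and drought-responsive chloroplast protein gene, differed most clearly between replicate numbers, with mean log2 signals of 5.88, 9.13 and 6.19 for numbers 1, 2 and 3 (2 arrays each), a spread of 9.52-fold (limma F test, adjusted p = 2.4e-05). COR47, a dehydrin gene, had 9.20, 10.26 and 9.03 (adjusted p = 0.000490). The auxin-responsive genes GH3.3 (4.61, 5.62 and 4.50; adjusted p = 0.0325), WES1 (5.74, 6.66 and 5.63; adjusted p = 0.0103) and IAA29 (7.10, 7.89 and 6.71; adjusted p = 0.0140) were also highest at number 2. AT3G16670 was lowest there (8.23, 6.85 and 8.77; adjusted p = 0.000107). In all, 743 probe sets (5.44%) passed the F test of the number in the fit with treatment, which was added after the data were seen; number 2 stood apart in 531 of them, 260 higher and 271 lower. All 3 tested auxin members passed (Fisher's exact test against the other probe sets, 1-sided, adjusted p = 0.000965 over 6 lists), as did 2 of 3 of the abscisic acid and water deficit list (adjusted p = 0.0257; the third, LTI30, was at 4.91, 5.64 and 5.81, highest at number 3, adjusted p = 0.0531) and BCAT4 of the aliphatic glucosinolate list (1 of 3, adjusted p = 0.309). None of the members tested in the cell wall, photosynthesis and phenylpropanoid lists passed. Fisher's test takes genes as independent, which members of 1 list need not be, so its p-values may be too small.

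**Figure D3:**
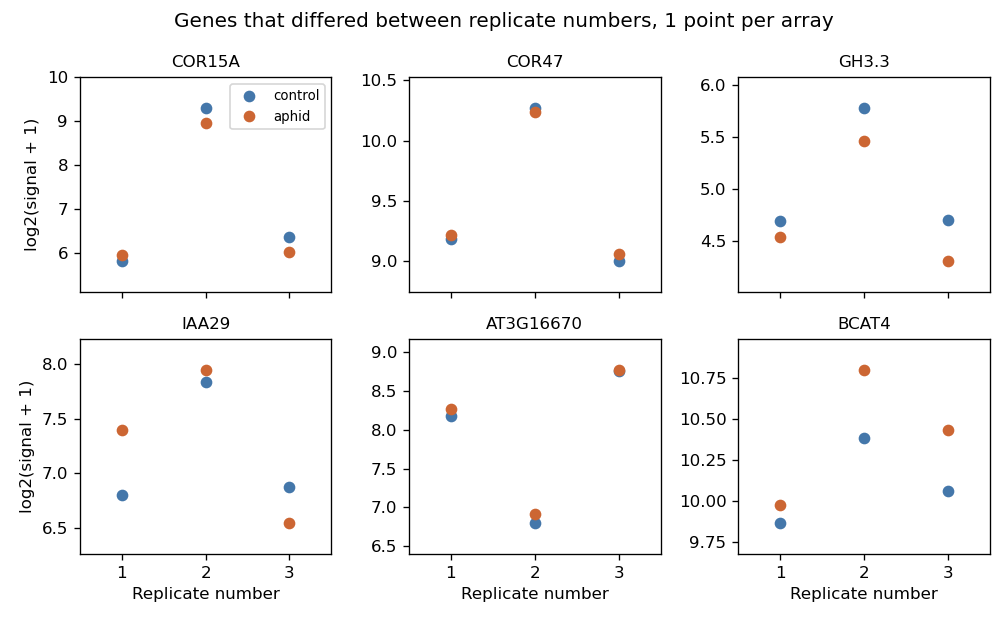
Log2(signal + 1) of 6 genes that differed between replicate numbers (horizontal axis), 1 point per array, control in blue and aphid in orange. COR15A, COR47, GH3.3, IAA29 and BCAT4 have their highest values and AT3G16670 its lowest on the arrays numbered 2, in both groups.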

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

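The block with a threshold of 0.1, the fits without both arrays numbered 2, the block with quantile normalization, all list members as 1 list, the symbol families and the F test of the number were chosen after the data were seen; the others were fixed before. No probe set passed 0.05 in any alternative run (limma; 387 to 1388 at an unadjusted p under 0.05), and the 7 past 0.1 needed the block. The count at an unadjusted p under 0.05 was 567, 1380 with the replicate block, 1388 with the block and quantile normalization, and 997 with no filter, where more probe sets are tested. The count of 10 at 2-fold became 1 and 0 with pseudocounts of 16 and 64, which shrink dim genes by construction, 266 with no filter, 4 with the stricter filter, 23 without both arrays numbered 2 and 6 to 39 on leaving out 1 array. The 1 list became 0 with a pseudocount of 64, no filter (3 lists tested), an estimated correlation, fry (1-direction test, which asks another question than camera) and all members as 1 list, and 0 to 1 on leaving out 1 array; with the stricter filter no list kept 5 members. The block changed no other call than those given. Of 518 values of the 32 named genes, 26 in 8 genes had the other sign, 0 passed 0.05, and the lowest adjusted p was 0.135. They were WRKY53 (0.0016 with a pseudocount of 64), STZ (0.026 quantile, 0.0052 median-centred, 0.015 array weights, 0.10 without both arrays numbered 2), SWEET11 (-0.0041 quantile), SAG101 (-0.0089 array weights) and GI (0.023 without both arrays numbered 2). On leaving out 1 array the ranges were -0.25 to 0.22 (SAG101), -1.17 to 0.90 (COR15A), -0.41 to 0.21 (WRKY53), -0.14 to 0.15 (STZ), -0.10 to 0.22 (SWEET11), -0.12 to 0.070 (GI), -0.20 to 0.50 (IAA29) and -0.24 to 0.012 (HSA32). These fits had no block, so the ranges include differences between numbers. Within pairs 1, 2 and 3, COR15A differed by 0.15, -0.35 and -0.33. The families passing fell from 4 without the block, and from 5 with it, to 0 with an estimated correlation, a test with few degrees of freedom here. The count of 743 for the replicate number became 191 with no filter. Where no construction is named, the cause was not tested. No background level or detection call was used here, so which signals lie above background was not tested.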

Other observations

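The symbol families, the other matchings, the tests of explanations and the counts of other splits were chosen after the result was seen; the comparisons of aphid with control arrays and the block were fixed before. Genes were grouped into 28 families of at least 5 tested members by the letters that open their symbols, with plastid-encoded genes as 1 family. The 5 tubulin genes with symbols in TUB were lower on the aphid arrays (5 of 5 negative, median log2 difference -0.24, camera adjusted p = 0.00268, but adjusted p = 0.437 with an estimated correlation), with TUB1 at -0.54 (SE 0.19) and TUB7 at -0.38 (SE 0.14). The autophagy genes with symbols in ATG were higher (7 of 8 positive, median 0.21, adjusted p = 0.00444, but adjusted p = 0.437 with an estimated correlation), with ATG8F at 0.28 (SE 0.09) and ATG8E at 0.35 (SE 0.18). Genes with symbols in CYP were higher too (12 of 13 positive, median 0.19, camera adjusted p = 0.00527, but adjusted p = 0.437 with an estimated correlation). CYP71B23 was at 0.47 (SE 0.32, and 0.14 with the block) and CYP71B26 at 0.43 (SE 0.35, and 0.12 with the block). Neither passed over all genes with the block (limma adjusted p = 0.274 and 0.249). Nearly all are cytochrome P450 genes, but CYP71 is a cyclophilin. The 69 plastid-encoded genes were higher by a median of 0.10 (56 positive, adjusted p = 0.00150, but adjusted p = 0.577 with an estimated correlation). With the block the UGT glycosyltransferases (15 of 21 positive, median 0.09) passed as well (adjusted p = 0.0480, 0.118 without it). With an estimated correlation 0 families passed, with or without the block, and no single member passed over all genes. The actin 3′ to 5′ ratios were higher on all 3 aphid arrays, and those of ubiquitin on the aphid array of each same-number pair, as given above.

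The plastid-encoded genes averaged -0.13, 0.41 and 0.03 in pairs 1, 2 and 3. Over pairs 1 and 3 the mean was -0.048, so the shift rests on pair 2, and after quantile normalization the median was 0.04 and the family no longer passed (adjusted p = 0.178). Their estimated correlation was 0.348, with which the camera p was 0.350, so correlated members are a candidate explanation for this call. For TUB, ATG and CYP the means had 1 sign in all 3 pairs, and the smallest adjusted p with an estimated correlation was 0.437. The estimated correlation of TUB was 0.232, so correlated members are a candidate explanation there too. Those of ATG and CYP were 0.0703 and 0.0182. As that test has few degrees of freedom with 6 arrays, it cannot decide for TUB, ATG or CYP. Their calls stay open, as does an effect of aphids or of the cage.

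Both arrays numbered 2 stood apart from the other 4. Scaling is argued against, since 725 probe sets passed the F test of the number after quantile normalization and 743 without it. RNA quality stays open: for 1 of 3 control genes (ubiquitin, 1.72 and 1.92) the array numbered 2 had the highest 3′ to 5′ ratio in both groups, while for GAPDH it had the lowest of the controls (0.890) and the highest of the aphid arrays (1.05), and control replicate 2 alone stood apart in hybridisation spikes (mean log2 signal 7.58, others 7.95 to 8.12) and 25S rRNA signal (21.7, others 95.6 to 202). A water deficit or cold response in the plants numbered 2 may contribute (Fisher's exact test of that list, which takes genes as independent, adjusted p = 0.0257). However, this rests on COR15A and COR47, with LTI30 highest at number 3 (5.81 against 5.64 at number 2). The auxin list passed too, and the design names no such treatment. Time of harvest stays open, as 1 of 18 clock list members was tested (GI, adjusted p = 0.342 for the number).

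Matching the control with the aphid arrays in the 5 other ways gave 0, 0, 0, 0 and 176 probe sets past the F test of the number, against 743 as deposited.

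The 6 arrays can be split 3 against 3 in 10 ways, too few for a share under 0.05. For probe sets past the adjusted threshold, the real split gave 0 and all 10 gave 0. At an unadjusted p under 0.05 the real split gave 567 and 6 of the 10 gave as many, the highest other being 1431. That split put both arrays numbered 2 and aphid replicate 3 on 1 side, which points to the structure by number; the value with the block was 1380. For differences of at least 2-fold the real split gave 10 and 5 splits gave as many, the highest other being 95, again with both arrays numbered 2 on 1 side; with the block the count was 14. For the cell wall list the real split gave 1 list and 2 splits did, the highest other giving 1. For the symbol families it gave 4 and 1 split, the real one, gave as many, the highest other giving 3. Of the 4 splits that part all pairs, fitted with the block, 1 gave as many as the real 1380 (itself), the highest other giving 678. Without the block these 4 gave 567 for the real split and 218, 261 and 343 for the others at an unadjusted p under 0.05. For differences of at least 2-fold they gave 10 against 3, 2 and 2. The real split was thus the highest of these 4, which are too few for a test. The 6 other splits keep pairs together.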
